A study of Escherichia coli with 2 samples.

How the data were processed

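Gene expression was measured in biofilm cells of 2 E. coli K-12 strains, a ydgG deletion mutant and the wild type BW25113, with 1 Affymetrix array per strain. Per the labels, overnight cultures were diluted 100-fold into 250 mL of medium in 1 L flasks with 10 g of glass wool, suspended cells reached an optical density at 600 nm of 5 after 24 h, and RNA from the biofilm was made into fragmented, labelled cDNA by the manufacturer's protocol. Samples were grouped by their titles. The description text of the sample titled as the deletion names the wild type, and the signal of ydgG itself, under the floor on both arrays, gave a weak check of this conflict.

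The deposited values are intensities, 1 per probe set on a linear scale, as the authors processed them. The software that summarised the probes, its background correction and its scaling target are not given in the sources used here. The values themselves show that both arrays share a 2% trimmed mean of 500.1 and 500.2, so they had been put on a common scale before deposit. Detection calls and single-probe signals were not used here, so a floor on the summarised signal stood in for them. Arrays were not read at different depths in the way sequencing libraries are, and the 1 array per strain limits the precision. The 99th percentile of signal was 4713 on the deletion array and 9838 on the wild-type array, and the log2 signals of the arrays had a Pearson correlation of 0.85 across probe sets.

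Probe sets were named through the platform annotation by Entrez identifier and given the current symbols of the ASM584v2 gene table. Of 7312 probe sets, 4398 were listed in the annotation. There, 3804 carried 1 distinct gene symbol and 594 several. By identifier, 4286 matched exactly 1 gene of the table, 42 matched several and 70 none, and the 2914 probe sets not listed stayed without a gene name. Ribosomal and transfer RNAs, other small RNAs, intergenic regions, control transcripts and phage, plasmid or vector sequences were recognised from the probe set names or the table and were kept out of gene counts, which left 4125 probe sets of 4081 genes. A gene with several probe sets took the brightest. 34 genes had several measured probe sets, and none of these disagreed in direction at 2-fold. The build behind the array design is not given in the sources used here, so no coordinates are printed.

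The deletion array was divided by 1.13, a log2 shift of 0.17, which set the median log2 ratio to 0 over the probe sets at or above the median of mean log2 signal. The floor was the 25th percentile of all values of both arrays after scaling, a signal of 174. Values under it were set to it, a gene under it on 1 array has a bound ("at least") and is not counted as within 2-fold when that bound is under 2-fold, and a gene under it on both has no ratio. Values under 1 were set to 1 before logarithms were taken. Genes were counted as higher or lower at a ratio of 2-fold, without a p-value, because 1 array per group allows no test. Each of 25 gene lists, with 522 entries of which 520 were on the array, was summarised by its median log2 ratio, with bounds taken at their value, and by the percentile of that median among 10000 random lists of the same size, matched on 10 bins of mean log2 signal. A list was said to stand apart when its median lay in the outer 5% of random lists, with 2.5% on each side, and lists under 3 measured members were given as values only. These percentiles treat genes as independent, and they describe these 2 arrays and not the strains. Correlations between neighbouring genes used the order of genes in the table. The comparison with pairs on opposite strands was not made, because strands were not used here.

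The groups, the scaling, the floor, the fold threshold, the gene lists, the naming rule and most alternatives were fixed before the data were examined. The lists covered AI-2, biofilm and motility regulators, flagella and chemotaxis, curli, type 1 fimbriae, colanic acid, other adhesins and exopolysaccharides, general stress, acid resistance, heat shock, cold shock, ribosomal proteins, ATP synthase, the TCA cycle, anaerobic respiration, tryptophanase, amino acid biosynthesis, iron uptake, phosphate starvation, multidrug efflux, sugar uptake, SOS, oxidative stress, genes deleted in the parent and the neighbours of ydgG. By the naming rule the text names ydgG and its neighbours, the 10 highest and 10 lowest genes above the floor on both arrays, the 3 largest bounds in each direction, up to 4 members of each list (the 2 highest and 2 lowest, leaving out members within 2-fold of lists that do not stand apart), 13 genes of AI-2, motility, adhesion and stress chosen beforehand, and the genes deleted in the parent. Other genes are summarised as counts.

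Alternatives were values as deposited, an equal trimmed mean, the median of all probe sets at 0, intensity-dependent scaling (lowess with a span of 0.3), quantile normalization, no floor or one at the 10th or 50th percentile, the floor value added to both signals, thresholds of 1.5-fold and 3-fold, genes above the floor on both arrays only, the mean of a gene's probe sets and the mean of list members. Alternatives added after the data were seen were scaling on control transcripts, subtraction of the median intergenic signal, leaving out probe sets marked as shared, and random lists matched on 40 bins of mean signal, on wild-type signal or on 40 bins of wild-type signal. A further one added then allowed for the correlation of neighbouring genes. In it the rank of each gene within 40 bins of mean signal was taken, and the median rank of a list was set against that of the same pattern of places moved along the gene order, in 3857 shifts of at least 50 places. This was repeated with bins of wild-type signal and with intensity-dependent scaling. The procedure was tested on simulated data for 4081 genes in the comparison of deletion with wild type, where it called 100% of genes raised 4-fold, 98% of genes lowered 4-fold and 1.08% of unchanged genes, and 3 of 100 random null lists stood apart. That simulated deletion array was the wild-type array with a constant shift and an assumed level of noise. Changed genes were drawn only from those well above the floor, and no trend of ratio with signal was put in. These shares check the procedure and give no error rate for the real arrays. In simulated ratios correlated along the gene order, 37 of 100 null runs of 10 neighbours stood apart from random lists of single genes and 7 of 100 stood apart from shifted lists. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.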

Results

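The series compared a ydgG deletion mutant of Escherichia coli K-12 with its wild-type parent BW25113, a laboratory strain widely used as the parent of single-gene deletions. ydgG, now named tqsA, encodes a membrane protein that has been linked to the transport of autoinducer 2 (AI-2), a signal molecule of quorum sensing. Both strains were grown for 24 h at 37 °C in LB medium with 0.2% glucose, in flasks shaken at 250 rpm that held 10 g of glass wool, and RNA was taken from the biofilm on the wool. Labelled cDNA from each strain was hybridised to 1 Affymetrix E. coli genome array. With 1 array per group there were no replicates, so no difference below could be set against a spread between cultures or arrays, and no test was possible. The number of arrays limits the precision of every value. Each array carried 7312 probe sets, of which 4125 reported 4081 named genes and 2886 reported intergenic regions. The median signal over all probe sets was 411 intensity units on the deletion array and 232 on the wild-type array.

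The ydgG probe set was read first, as a check of the labels, because the free-text description of the sample titled as the deletion calls it wild type. Its signal was 10.6 on the array titled as the deletion and 129 on the wild-type array. No gene probe set had a lower signal than ydgG on the deletion array. On the wild-type array, 11.9% of gene probe sets and 42.7% of intergenic probe sets lay below it, so ydgG was itself dim in the parent. After scaling, the log2 ratio of deletion over wild type was -3.78, but both signals were under the floor of 174 and the wild-type one was under the intergenic median of 145, so this value is no measured fold and the check is weak. The titles were followed throughout, and the lower ydgG signal lay on the array whose title names the deletion. The extent of the deleted segment relative to the probes was not given in the sources used here.

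**Figure D1:**
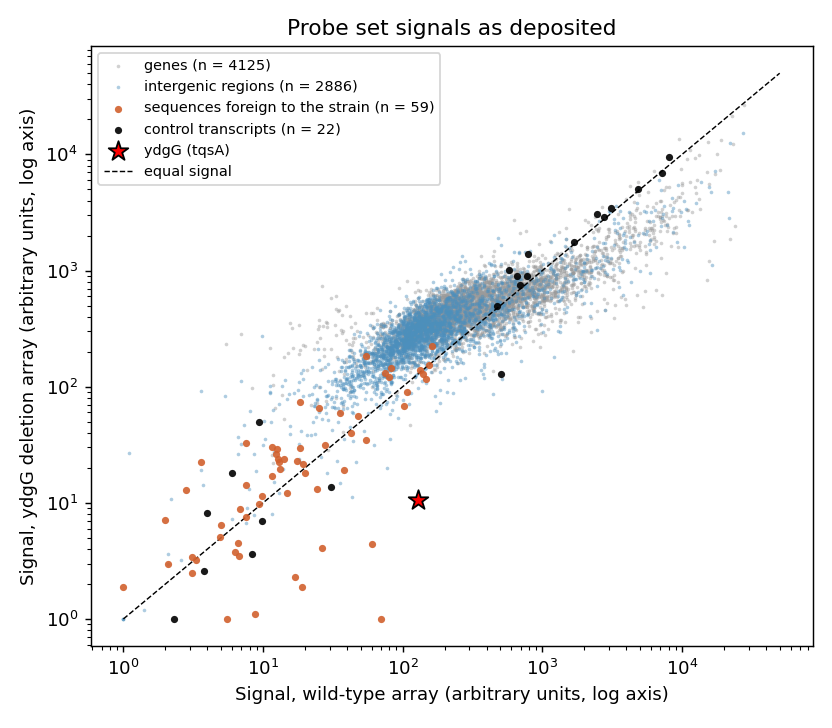
Signal of each probe set on the wild-type array (x axis) and on the ydgG deletion array (y axis), both in arbitrary intensity units on log axes, 1 array per strain, as deposited; values below 1 are drawn at 1. Grey and blue points are genes and intergenic regions, orange points are phage, plasmid and vector sequences, black points are control transcripts, the star is ydgG at 129 and 10.6, and the dashed line marks equal signal; dim genes and intergenic regions lie above the line and the brightest genes below it.

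The comparison asked which genes were expressed differently in biofilm cells that lack ydgG. The genes furthest below the wild type were those of acid resistance and of ribosomal proteins, and genes of ATP synthase were also lower as a group. Smaller group shifts, lower for the tricarboxylic acid (TCA) cycle and higher for flagella and chemotaxis and for colanic acid, a capsular polysaccharide, depended on how the correlation of neighbouring genes and the signal level were allowed for. Of 3956 genes above the floor on at least 1 array, 520 were at least 2-fold higher in the deletion strain, 406 were at least 2-fold lower and 2451, above the floor on both arrays, were within 2-fold. The remaining 579 genes were under the floor on 1 array and had only a bound under 2-fold, so they could not be placed; 566 of them were under it in the wild type. For 208 of the higher and 2 of the lower genes the ratio was also a bound. Without a floor 929 genes were at least 2-fold higher and 408 at least 2-fold lower. The higher genes were 13.1% of those measured, and 13.7% of measured intergenic probe sets were also at least 2-fold higher. The counts of genes moved with signal level. As deposited, the median log2 ratio ran from 1.31 in the dimmest of 10 equal bins of probe sets to -0.88 in the brightest bin, with 0.76 over all probe sets. When this trend was removed by intensity-dependent scaling, 92 genes were at least 2-fold higher and 201 at least 2-fold lower, of which 61 and 117 were among those of the main scaling. The share of higher genes among those at least 2-fold apart was 56.2% with the main scaling and 31.4% with intensity-dependent scaling. Each gene list is therefore described against random lists of the same size and signal level. Such lists treat genes as independent, which members of 1 operon are not, so each list was also set against its own pattern of places moved to 3857 other positions along the gene order. In that comparison acid resistance, ribosomal proteins and ATP synthase stood apart as lower, at percentiles 0.078, 0 and 0.285, and also did so with bins of wild-type signal in place of mean signal and with intensity-dependent scaling.

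Acid resistance genes showed the lowest list median. Of 14 measured members, 9 were at least 2-fold lower, 2 at least 2-fold higher, 1 within 2-fold and 2 had only a bound, and the median log2 ratio of -2.47 lay below those of all 10000 matched random lists, whose median was -0.73. gadC, the glutamate and γ-aminobutyrate antiporter, had a signal of 15156 in the wild type and 831 in the deletion strain and was 20.6-fold lower after scaling. The glutamate decarboxylase genes gadA and gadB were 14.4-fold and 13.3-fold lower, and gadE, which encodes the main activator of this system, was 13.2-fold lower. hdeA and hdeB, which encode periplasmic acid chaperones, were 11.1-fold and 10.7-fold lower, and the neighbouring membrane protein gene hdeD was 12.2-fold lower. These 7 genes were among the 10 with the lowest ratios of the genes above the floor on both arrays. With intensity-dependent scaling the differences were smaller, at 8.83-fold for gadC, 6.05-fold and 5.77-fold for gadA and gadB, 6.30-fold for gadE, 4.90-fold and 4.55-fold for hdeA and hdeB and 6.36-fold for hdeD. The arginine decarboxylase gene adiA and the lysine decarboxylase gene cadA, which belong to separate acid resistance systems, were 2.29-fold and 2.16-fold higher. These 7 members stayed at least 2-fold lower with that scaling, and adiA and cadA were then within 2-fold, at log2 ratios of 0.67 and 0.50.

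Ribosomal protein genes were lower almost throughout the list. Of 54 measured, 50 were at least 2-fold lower, none was at least 2-fold higher, and the median log2 ratio was -1.87 against -0.89 for matched random lists, below all 10000 of them. The lowest were rplC at 10.7-fold, rpsC at 9.30-fold and rpsR at 9.30-fold below the wild type, and these completed the 10 lowest genes above the floor on both arrays. With intensity-dependent scaling they were 5.14-fold, 5.66-fold and 9.40-fold lower. rpsT and rplS lay within 2-fold, at log2 ratios of -0.43 and -0.66. That scaling left 27 of the 54 at least 2-fold lower, with a list median of -0.99.

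The 9 genes of the ATP synthase operon had a median log2 ratio of -1.65 against -0.29 for random lists, and 7 were at least 2-fold lower. atpB, at 4.06-fold, and atpF, at 3.94-fold, both for subunits of the membrane sector, were the lowest, while atpC and atpD lay within 2-fold at -0.78 and -0.83. With intensity-dependent scaling 5 members were at least 2-fold lower, 4 of the 7 and atpD, at 2.58-fold. In the TCA cycle and glyoxylate shunt, 15 of 17 genes were at least 2-fold lower and the median was -1.53 against -0.95, at percentile 0.19 of the random lists. aceA, for isocitrate lyase of the glyoxylate shunt, was 6.57-fold lower and sucC, for a subunit of succinyl-CoA synthetase, was 4.11-fold lower. The fumarase genes fumA and fumC lay within 2-fold, at -0.13 and 0.63. With intensity-dependent scaling only 2 of the 17 were at least 2-fold lower, aceA and sucC were 2.79-fold and 1.77-fold lower, and fumA turned to 0.63 with fumC at 0.10. With random lists matched more finely on wild-type signal the TCA list no longer stood apart, at percentile 3.13. Nor did it against its pattern moved along the gene order, at percentile 4.20, or 11.8 in bins of wild-type signal.

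**Figure D2:**
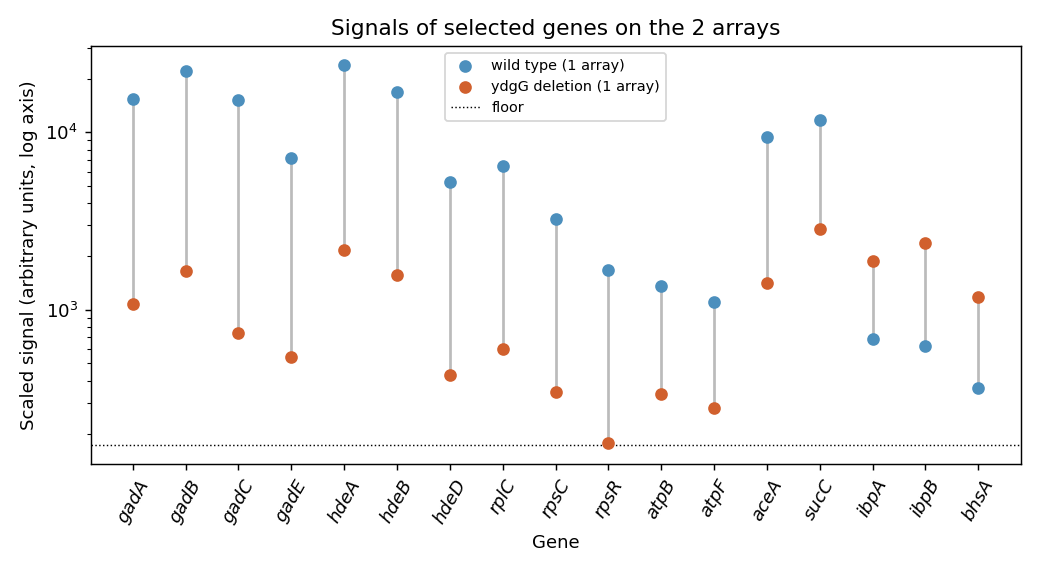
Scaled signal (y axis, arbitrary intensity units, log axis) of selected genes (x axis) on the wild-type array (blue) and the ydgG deletion array (orange), 1 array each; grey lines join the 2 values of a gene and the dotted line is the floor. gadC had 15156 in the wild type and 737 in the deletion strain, and ibpB had 625 and 2397.

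Flagella and chemotaxis genes were dim on both arrays, and as a group they were higher in the deletion strain than random lists of equal signal. Of 51 measured members, 17 were at least 2-fold higher, none was at least 2-fold lower, 25 were within 2-fold and 9 had only a bound under 2-fold, while without a floor 23 were at least 2-fold higher. The median log2 ratio was 0.87 against 0.62 for random lists, at percentile 99.95. A split by symbol, made after the data were seen, placed 13 of 20 fli genes at least 2-fold higher, at percentile 99.99. The flg, flh and che genes did not stand apart, at 71.5, 41.8 and 91.2, with 2 of 14, 0 of 5 and 2 of 6 higher. Moved along the gene order, the fli genes stood apart at 98.0, but not in bins of wild-type signal, at 97.3. fliO, for a part of the flagellar export apparatus, was 3.47-fold higher, and flgC, for a rod protein, was at least 3.32-fold higher. The flagellin gene fliC and the master regulator gene flhD were within 2-fold, at log2 values of -0.05 and 0.36, and flhD turned to -0.33 with intensity-dependent scaling. The motor gene motA, under the floor in the wild type, had a bound of at least 0.70, which leaves open whether it reached 2-fold. In the colanic acid list, 9 of 19 measured genes were at least 2-fold higher and none at least 2-fold lower, with a median of 0.99 against 0.74, at percentile 99.68. The glycosyltransferase gene wcaA was at least 3.64-fold higher and rcsA, which encodes an activator of capsule synthesis, was 2.76-fold higher, while wzb and cpsG lay at 0.24 and 0.31. With intensity-dependent scaling rcsA was 1.77-fold higher, wzb turned to -0.59 and cpsG was at 0.35. That scaling left 3 flagellar and 2 colanic acid genes at least 2-fold higher, and against random lists both still stood apart, at percentiles 99.65 and 98.19. The colanic acid list no longer stood apart when the floor was removed, at percentile 96.0. Against their own patterns moved along the gene order neither list stood apart in bins of mean signal with the main scaling, at percentiles 96.7 for flagella and 94.4 for colanic acid, whereas in bins of wild-type signal both did, at 97.7 and 98.1. With intensity-dependent scaling the flagellar list did, at 99.65, and the colanic acid list did not, at 96.2.

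The genes with the highest ratios came from several functions. ibpB, for a small heat shock chaperone, was 3.83-fold higher, and its operon partner ibpA was 2.74-fold higher. bhsA, for an outer membrane protein linked to stress and biofilm formation, was 3.29-fold higher. ytfE, for a protein of iron-sulfur cluster repair, was 3.44-fold higher, and the galactose permease gene galP was 3.08-fold higher. The other genes among the 10 highest were tfaD, dmsD, rlhA, chbR and ulaB, at 3.06-fold to 3.21-fold, besides fliO. In the wild type, ytfE, dmsD, chbR, fliO, tfaD, galP and ulaB had signals of only 174 to 203, at or little above the floor of 174. These also lay under 262, the 75th percentile of intergenic signal on that array, so their folds are uncertain. ibpB, ibpA and bhsA were also at least 2-fold higher with intensity-dependent scaling, at 6.80-fold, 4.70-fold and 3.80-fold, whereas dmsD and chbR were then within 2-fold. Among genes under the floor in the wild type, purC, yodB and rlmI had the largest bounds, at least 4.16-fold, 4.08-fold and 3.77-fold higher. Among genes under it in the deletion strain, pheL and hisQ were at least 2.54-fold and 2.18-fold lower, and nrdE had a bound of 1.72-fold.

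**Figure D3:**
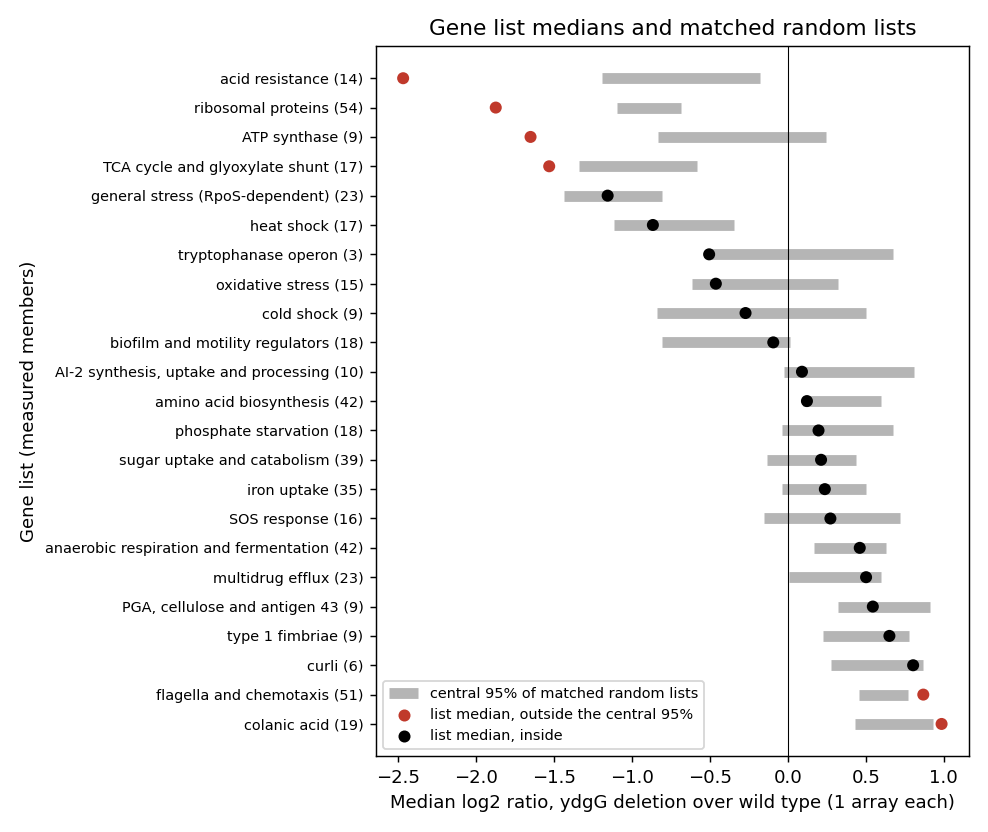
Median log2 ratio of deletion over wild type (x axis, 1 array each) of each gene list (y axis, with its number of measured members), red where it lies outside and black where it lies inside the grey bar, which spans the central 95% of 10000 random lists of the same size and signal level. Acid resistance, at -2.47, ribosomal proteins, ATP synthase and the TCA cycle lie below their bars, and flagella, at 0.87, and colanic acid, at 0.99, lie above theirs; the bars treat genes as independent.

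Genes of AI-2 synthesis, uptake and processing differed little. Of 10 measured, 9 were within 2-fold and the list median of 0.09 did not stand apart from random lists, at percentile 6.88. luxS, the AI-2 synthase gene, was 2.11-fold lower, but at -0.23 it was within 2-fold with intensity-dependent scaling. lsrB, for the AI-2 binding protein, and lsrR, for the repressor of the lsr operon, had log2 ratios of -0.02 and 0.02. Among 18 regulators of biofilm and motility, 1 was at least 2-fold higher and 3 at least 2-fold lower, and the list lay at percentile 92.5. The higher gene was bhsA, and the lower genes were the neighbours ymgA, ariR (ymgB) and ymgC, at 4.26-fold, 4.46-fold and 4.23-fold, of which ariR has been linked to biofilm formation and acid resistance. ymgC lies outside the naming rule and was named after its values were seen. With intensity-dependent scaling this list lay higher, at percentile 98.0 of random lists but 94.6 of its pattern moved along the gene order, while with the main scaling that pattern gave 96.7 in bins of mean signal and 99.5, which is apart, in bins of wild-type signal. With intensity-dependent scaling ymgC was still 4.56-fold lower, while ymgA, at -0.84, and ariR, at the edge of the threshold, were within 2-fold. qseB, a response regulator gene linked to flagellar control, was at 0.86.

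Genes for surface structures other than flagella and capsule did not stand apart as lists. Of 6 measured curli genes, the fibre subunit gene csgA was just within 2-fold, at 0.97, and the other 5 were under the floor in the wild type with bounds under 2-fold, such as at least 0.57 for the regulator gene csgD. Without a floor 5 of 7 curli genes were at least 2-fold higher. Of 9 type 1 fimbriae genes, fimH, for the adhesin, was 2.48-fold higher, fimA, for the major subunit, was 2.04-fold lower, 1 was within 2-fold and 6 had only bounds. Without a floor 6 of the 9 fimbriae genes were at least 2-fold higher, and with intensity-dependent scaling none was, while fimA was 3.15-fold lower. Of 9 genes for poly-N-acetylglucosamine, cellulose and antigen 43, pgaC was at least 2.31-fold higher and bcsC 2.23-fold lower, neither of which reached 2-fold with intensity-dependent scaling. flu, which encodes antigen 43, had a bound of at least 0.54.

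Stress lists were largely at the level of random lists of equal signal. Of 23 genes of the RpoS-dependent general stress response, 14 were at least 2-fold lower and none higher, but the median of -1.16 was close to the -1.10 of random lists, at percentile 36.6, and with intensity-dependent scaling none was at least 2-fold lower. rpoS itself was 2.87-fold lower, the catalase gene katE 3.37-fold lower and glaH (csiD) 3.78-fold lower. Of 17 heat shock genes, 2 were higher, ibpA and ibpB, and 5 were lower, including the chaperonin genes groS at 2.90-fold and groL at 2.76-fold. With intensity-dependent scaling 3 heat shock genes were at least 2-fold higher and none lower, and groS and groL were 1.22-fold and 1.61-fold lower. In the cold shock list, 1 of 9 genes, nusA, was 2.67-fold lower, or 1.51-fold with intensity-dependent scaling. Of 16 SOS genes, 3 were higher, including dinF at 2.78-fold and dinI at 2.76-fold, and sbmC was 2.18-fold lower. With intensity-dependent scaling no SOS gene was at least 2-fold higher, dinF and dinI were at 1.75-fold and 1.77-fold, and the direction of sbmC turned, at 0.054. Of 15 oxidative stress genes 3 were lower, including ahpC at 3.05-fold and sodA at 2.69-fold, which became 1.28-fold and 1.33-fold with intensity-dependent scaling.

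Lists of metabolism and transport did not stand apart from random lists either, and most of their 2-fold differences were lost with intensity-dependent scaling. Of 42 genes of anaerobic respiration and fermentation, 7 were higher, led by hycF at 2.58-fold and dcuC at 2.40-fold, and 3 were lower, including hyaA at 2.08-fold and pflB at 2.08-fold. With intensity-dependent scaling 2 were higher, including hycF, and 1 was lower, and the direction of pflB turned, at 0.084. Of 3 tryptophanase operon genes, the leader gene tnaC was 3.90-fold lower, or 2.01-fold with intensity-dependent scaling, and tnaA, for the enzyme, lay at -0.50, or -1.11 with that scaling. These 3 genes stood apart as lower only when moved along the gene order in bins of wild-type signal, at percentile 2.48. The 42 amino acid biosynthesis genes had a median log2 ratio of 0.12, on the lower side of random lists, whose median was 0.36, at percentile 3.98. Of the 42, 6 were higher, led by argI at 2.31-fold and ilvC at 2.30-fold, and none was lower, where 13.1% of all measured genes were higher. With intensity-dependent scaling 1 was higher and 1 lower, and argI and ilvC were at 1.83-fold and 1.69-fold. Among 35 iron uptake genes 2 were higher, fepE at least 2.89-fold and entD at least 2.19-fold, and 3 were lower, including entB and entC, both at 2.11-fold, against 1 higher, fepE, and 1 lower with intensity-dependent scaling. Of 18 phosphate starvation genes 3 were higher, including phoE at least 3.16-fold and phnC at least 2.58-fold. With intensity-dependent scaling 2 were higher, including phoE at 2.20-fold, phnC had a bound of 1.93-fold and 1 other member was lower. Of 23 multidrug efflux genes 3 were higher, including mdtI and mdtJ, and the outer membrane channel gene tolC was 2.59-fold lower, or 2.40-fold with intensity-dependent scaling. Among 39 genes of sugar uptake and catabolism 7 were lower, led by gatA and gatZ of galactitol use at 3.74-fold each, and malF and srlD were 2.06-fold and at least 2.27-fold higher. With intensity-dependent scaling 3 sugar genes were lower and 1 higher, gatA and gatZ were 1.68-fold and 1.61-fold lower, and malF and srlD were 1.37-fold and at least 1.61-fold higher.

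Of 5 genes around ydgG on the chromosome, 2 were at least 2-fold higher and 3 were within 2-fold. mdtI and mdtJ, which encode a small multidrug and spermidine exporter and lie directly before ydgG in the gene order of the ASM584v2 table, were at least 2.52-fold and 2.74-fold higher. With intensity-dependent scaling mdtJ was 2.29-fold higher and mdtI 1.65-fold higher, so 1 of the 5 reached 2-fold. pntB and pntA, for the membrane-bound transhydrogenase on the other side, lay at 0.66 and -0.35, and ydgH lay at 0.70. With intensity-dependent scaling pntB and pntA were at 0.20 and -0.17, and ydgH turned to -0.052. The 5 genes together did not stand apart from random lists. Of 7 genes in regions known to be deleted in BW25113, araA, araB, rhaA and rhaB were under the floor on both arrays. araD, rhaD and lacZ had signals of 778, 478 and 353 in the deletion strain and 312, 337 and 113 in the wild type, against a floor of 174. Whether the deletions cover the sequence read by these probe sets was not checked. The control transcripts Dap, Lys, Phe and Thr, read by 12 probe sets, had a median log2 ratio of 0.15 as deposited, from -0.05 to 0.81. Of the other control probe sets only BioB-5 and BioC-3 were above the floor on either array, and BioB-5 lay at 0.81 and BioC-3 at -1.98, with a signal of 128 in the deletion strain and 504 in the wild type, and E. coli has bio genes of its own.

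Ratios of genes next to each other in the gene order went together. Across 3506 pairs of adjacent genes, Spearman's correlation of the log2 ratios was 0.42, against 0.06 for genes 10 places apart and a range of -0.03 to 0.03 in random pairs. It was 0.26 with intensity-dependent scaling. These are correlations across genes on 1 pair of arrays, and genes are not independent replicates.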

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

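The gene and intergenic comparison was laid down before its result was seen; the other tests in this part were chosen after the patterns had been seen. Intergenic probe sets gave a signal outside the gene comparison. As deposited, 1456 of 2886 intergenic probe sets, or 50.5%, were at least 2-fold higher on the deletion array and 151 were at least 2-fold lower. Their median log2 ratio as deposited was 1.01, against 0.60 for gene probe sets. With the main scaling and floor, 309 of 2263 measured intergenic probe sets, or 13.7%, were higher and 171 lower. The share of measured genes that were higher was nearly the same, 13.1%, so intergenic probe sets did not stand out there.

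The rise took in dim probe sets of the chromosome in general, genes and intergenic regions alike. A rise confined to the sequence of genes is argued against, because 1733 dim gene probe sets exceeded intergenic ones of equal wild-type signal by a median of only 0.19 (95% bootstrap interval 0.17 to 0.22, log2), inside the margin of 0.3 set for it. Intergenic probe sets were not split by whether they lie in the transcribed ends or spacers of gene transcripts. A rise of gene transcripts that includes such parts therefore stays open. Scanner background or scaling of the whole array would raise phage, plasmid and vector probe sets too. As deposited, 59 of these had a median log2 ratio of 0.19, with median signals of 14.8 and 19.6 on the wild-type and deletion arrays. Intergenic ones had 1.01, with 145 and 304, which argues against that explanation. Of the 59, 38 lay within the intergenic range of signal. There, 36 of 38 rose less than intergenic ones of equal wild-type signal, by a median of -1.15 (-1.47 to -0.87). The match was on the denominator of the ratio and took dim intergenic values. Such values tend to rise on any other array, so this size cannot be read. Chromosomal DNA or chromosome-wide RNA carried into the labelled deletion sample may account for the rise and stays open, since the 7 genes from regions deleted in the parent gave a median excess of -0.48 with an interval from -1.43 to 0.32, with 4 below 0 and araD, lacZ and rhaD above it, and whether the deletions cover these probe sets was not checked. A true rise of weak transcription in the deletion strain was not tested, because strain and array coincide. The intervals in this paragraph resample single probe sets of 1 pair of arrays as if they were independent. They cover no spread between cultures or arrays, and they are too narrow where neighbouring probe sets go together.

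Acid resistance and ribosomal protein genes, bright in the wild type, were lower on the deletion array. Compression of bright signals on that array could lower them, but against random lists matched on 40 bins of wild-type signal the acid resistance median was still shifted by -1.44 and the ribosomal median by -0.63, below all random lists in both cases, and against patterns moved along the gene order in the same bins they lay at percentiles 0.052 and 0, so compression is argued against as the whole cause. A difference between the 2 cultures unrelated to the deletion, such as in growth phase or pH, cannot be told apart from an effect of the deletion with 1 array per group. An effect of losing ydgG on these genes therefore stays a hypothesis.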

How the results depend on the processing

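Scaling to control transcripts, subtracting intergenic signal, leaving out shared probe sets, the other matchings of random lists and lists moved along the gene order were tried only after the data were seen. No paired analysis was possible because each group had 1 array and the replicate number is only a name. The count of higher genes moved with most scalings and with every change of the floor. The count of lower genes moved with some scalings and changed less with the floor. Both moved with the threshold by its construction. From 520 genes at least 2-fold higher, the count went to 841 as deposited and with equal trimmed means, 43 with the median of all probe sets at 0, 92 with intensity-dependent scaling, 140 with quantile normalization, 929 without a floor, 847 and 71 with a floor at the 10th and 50th percentile, 92 with the floor value added, 1446 and 31 at 1.5-fold and 3-fold, and 312 for genes above the floor on both arrays. From 406 lower genes it went to 895 with the median of all probe sets at 0, 201 with intensity-dependent scaling, 215 with quantile normalization, and 711 and 144 at 1.5-fold and 3-fold. The median shift of all probe sets as deposited, 0.76, was removed only by the median of all, lowess and quantile scalings. The ydgG log2 ratio of -3.78 went to -4.37 with the median of all probe sets at 0, -4.86 with intensity-dependent scaling, -4.51 with quantile normalization, -0.72 with the floor value added and a bound of -0.38 with a floor at the 10th percentile, and had no value with one at the 50th.

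Acid resistance, ribosomal protein and ATP synthase genes stood apart as lower under each alternative run. Against lists moved along the gene order in bins of mean signal, flagella at percentile 96.7, colanic acid at 94.4 and the TCA list at 4.20 no longer stood apart. In bins of wild-type signal flagella and colanic acid did, at 97.7 and 98.1, and the TCA list, at 11.8, did not. With intensity-dependent scaling flagella did, and colanic acid at 96.2 and the TCA list at 4.21 did not. The TCA list also failed with 40 bins of wild-type signal, where its shift from random lists was -0.35. The colanic acid shift no longer stood apart at 0.25 without a floor, 0.24 and 0.13 with a floor at the 10th and 50th percentile, 0.15 with the floor value added and 0.42 after intergenic subtraction. Regulators of biofilm and motility stood apart at 0.34 with intensity-dependent scaling, at 0.33 with 40 bins of wild-type signal and, at percentile 99.5, when moved along the gene order in such bins, where the tryptophanase list did so at 2.48. Amino acid biosynthesis did so at -0.30 without a floor, -0.31 with a floor at the 10th percentile and -0.20 with the floor value added, and genes deleted in the parent at 0.48 with the median of all probe sets at 0 and -0.38 with the floor value added, and at percentile 99.3 when moved along the gene order with intensity-dependent scaling. The cause of these list shifts was not tested. pflB and sbmC reversed, to 0.084 and 0.054 with intensity-dependent scaling and 0.15 and 0.12 with quantile normalization. Of 74 genes covered by the naming rule and at least 2-fold apart, 36 were so with intensity-dependent scaling and 42 with quantile normalization. Signals near the intergenic level, 145 in the wild type and 304 in the deletion strain at the median, limit what can be said of dim genes.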

Other observations

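All tests in this part were chosen after the main results were seen. Genes were also grouped by the first 3 letters of their symbols, which often marks a shared pathway, and the 185 groups with at least 5 measured members were set against matched random lists. 19 groups stood apart as lower and 9 as higher, where random lists of independent genes give about 4.6 in each direction, and 13 and 7 of them also stood apart with intensity-dependent scaling. Against their own patterns moved along the gene order, which keeps operons together, 14 stood apart as lower and 8 as higher. Of these, 11 and 5 also did so with intensity-dependent scaling. In bins of wild-type signal 10 stood apart as lower and 4 as higher. These 4 are no more than the 4.6 or so that the same tail would give by chance. Among the lower groups outside the lists above, all 5 dpp genes of dipeptide uptake were at least 2-fold lower, with a median log2 ratio of -1.69 against -0.45 for random lists. The glg genes of glycogen metabolism had a median of -1.17 against -0.46, with 4 of 6 at least 2-fold lower. The waa genes of lipopolysaccharide core synthesis were within 2-fold in 11 of 13 measured cases, with 1 higher and 1 with only a bound, yet their median of -0.15 lay under the 0.48 of random lists of equal signal, at percentile 0.02. The paa genes of phenylacetate degradation had a median of -0.38 against 0.21.

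Among the higher groups, the bio genes, mostly of biotin synthesis, had a median of 1.10 against 0.50. Of these 7 genes, 4 were at least 2-fold higher, 1 was within 2-fold and 2 had only a bound. The control probe sets BioC-3 and BioB-5, kept out of the gene counts, lay at -1.98 and 0.81 as deposited. How far they read the bio genes of the strains was not checked. The dgc genes, which encode diguanylate cyclases that make the biofilm-related second messenger cyclic di-GMP, had a median of 0.96 against 0.57, with 4 of 11 at least 2-fold higher, at percentile 99.2. The tor genes of trimethylamine N-oxide respiration lay at 1.03 against 0.52 and the ssu genes of sulfonate use at 1.23 against 0.66. With intensity-dependent scaling no bio, dgc or ssu gene was at least 2-fold higher, and 1 of 7 tor genes was. With that scaling 4 of 5 dpp, 1 of 6 glg and 2 of 14 paa genes were at least 2-fold lower. All 8 groups named so far also stood apart from random lists with intensity-dependent scaling, where the dgc median was 0.43 and the dpp median was -1.22. They come from the 13 lower and 7 higher groups that stood apart with both scalings, so this adds no support. Under the other scalings the 8 groups stood apart too, except dgc with the median of all probe sets at 0, at percentile 96.3. The sign of the waa median itself turned as deposited, at 0.017. Against patterns moved along the gene order dpp, glg, waa, paa, tor and ssu stood apart with both scalings, bio, at percentile 96.3, with neither, and dgc, at 96.8 with the main scaling, only with intensity-dependent scaling. In bins of wild-type signal glg, at 5.69, and bio, at 92.1, did not stand apart and the other 6 did, with dgc at 99.8. The din group, part of which is in the SOS list, also lay higher, at 1.15 against 0.61, with 3 of 6 genes at least 2-fold higher. It stood apart from random lists and from moved patterns with both scalings, and in bins of wild-type signal, at percentile 99.9. Of the other groups outside the lists that stood apart from random lists with both scalings, phe and sec lay lower and idn higher. With the main scaling they were at percentiles 0.03, 0.18 and 99.7. Other scalings were not run for the din, phe, sec and idn groups. Single groups near the outer 2.5% can arise by chance. In bins of wild-type signal dgc, tor, ssu and din were the only higher groups apart from moved patterns. That is no more groups than chance gives, so their count adds no support.

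As deposited, 18 probe sets of ribosomal RNA had a median log2 ratio of 0.27 and 7 probe sets of other small RNAs had 0.26, while 48 transfer RNA probe sets had -0.35. The sign of the ribosomal and small RNA medians turns when the median of all probe sets, 0.76, is set to 0.

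mdtI and mdtJ, beside ydgG, were set against the 200 genes nearest to each in wild-type signal. The ratios were as deposited and without a floor, and mdtI was under the floor in the wild type, so its rank is uncertain. mdtI had a higher ratio than 92.5% of them and mdtJ than 99%, while the values for pntB, pntA and ydgH were 61%, 48% and 43%.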
